A study of Mus musculus with 12 samples.

How the data were processed

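RNA of 12 macrophage samples was measured on 12 single-colour arrays, 1 array per sample without pooling: 2 wildtype and 2 Commd1 knockout mice, each untreated and after 3 h and 24 h of LPS at 10 ng/mL. Each scanner file holds 43020 spots that are not controls. Per the file headers, it gives for each spot a processed intensity, made by subtracting background and a spatial trend within the array, without scaling between arrays. The program was Agilent Feature Extraction 10.7.3.1 (named in the submitters' processing notes). Raw mean and background intensity and flags for spots above background, saturated or uneven are also given per the file headers. The deposited value table is on a log2 scale: on each array, 99.6% to 100% of probes well above background equal the array's own log2 processed signal minus a constant within 0.01, and dim probes are raised to a floor. Its column medians were -4.37 and -4.46 for untreated wildtype, -4.33 and -4.41 for untreated knockout, -4.42 and -4.40 for wildtype 3 h, -4.30 and -4.38 for knockout 3 h, -4.44 and -4.42 for wildtype 24 h and -4.33 and -4.51 for knockout 24 h, so it is not centred per gene.

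Groups and mice were taken from the labels, which give 1 mouse per replicate number within a genotype, so the 3 samples of a mouse are paired. Residuals of the same mouse correlated across genes with r of 0.19, 0.13 and 0.15 in wildtype and 0.36, 0.13 and 0.12 in knockout (untreated with 3 h, untreated with 24 h, 3 h with 24 h). The arrays lay on 3 slides of 4, 1 slide per time, with wildtype and knockout on fixed positions, so slide and LPS time cannot be told apart. A genotype comparison lies within 1 slide, where genotype and array position cannot be told apart. On the untreated and 3 h slides the slope of log2 signal on spike-in amount was 0.735 to 0.743 in wildtype and 0.794 to 0.799 in knockout arrays, and at 24 h 0.820 to 0.824 and 0.842 to 0.869. No spot was saturated. Outlier spots numbered 132 to 214 per array and 589 (1.01% of spots uneven) on replicate 1 of the knockout 24 h group.

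Control spots and spots marked as outliers were left out, spots of 1 probe were averaged, and log2 processed signals were reduced by the array's 75th percentile, giving 39429 probes. Probes were given gene symbols through the reference table by accession (26412), symbol (3855) or synonym (734), and 8428 kept the name in the file, so that 78.6% were matched. They stood for 31693 gene names, 23606 of them matched to the reference. Coordinates are those of the files (mm9). A probe entered if it was well above background on both arrays of at least 1 group (28413 probes), and the probe with the highest mean stood for its gene (4565 genes had more than 1), which left 22968 genes, 18031 of them matched. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and in R 4.3.3 with limma 3.58.1 and statmod 1.5.0.

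All 12 arrays were fitted in limma with a mean per group and moderated variances (6 residual degrees of freedom, 2.23 prior), and contrasts gave LPS 3 h and 24 h against untreated in each genotype, 24 h against 3 h in wildtype, knockout against wildtype at each time, and the differences of the LPS responses (interaction). The genotype difference over times was fitted to 4 mouse means. Tests were two-sided with Benjamini-Hochberg adjustment over all genes at 0.05. A gene is said to rise, fall or be higher or lower only past that threshold. Values after ± are standard errors on the log2 scale unless SD is written. Where a gene was not well above background on either array of its lower group, only a lower bound of the fold is given, computed against the array's lowest detected signal, and list medians are given also with such members at their bounds where that changes them. For differences of the LPS response no bounds were computed: single genes below background in a group compared are given without a size (except 1 that lost its direction in an alternative), and list medians include such members as processed.

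Lists of genes were tested with limma's camera at a preset correlation of 0.01 between genes and, as the alternative, with the correlation estimated, adjusted over the 28 lists with at least 3 measured members (29 were fixed; the sex-linked list was too small). They were inflammatory cytokines, chemokines, NF-kB family and feedback, interferon-stimulated genes, immediate early and MAPK feedback genes, MHC class II and costimulation, alternative activation, antimicrobial and tissue effectors, proliferation, copper homeostasis, the COMMD family and CCC or retriever complexes, hypoxia-inducible genes, oxidative phosphorylation, NRF2 and oxidative stress, cholesterol synthesis and uptake, unfolded protein response, lysosome and phagocytosis, heat shock, and markers of macrophages, dendritic cells, neutrophils, B cells, T and NK cells, erythroid cells, megakaryocytes, mast cells with basophils and eosinophils, stroma and osteoclasts. Cd40, Ccl22 and other genes stand in more than 1 list, and macrophages express many markers of the dendritic cell and osteoclast lists.

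The lists, comparisons, tests, alternatives and the rule for naming genes were fixed before the data were examined. The rule named Commd1; for each comparison, among genes with a symbol that passed and whose arrays of 1 group all lay above those of the other, the 12 with the largest change in each direction (6 for 24 h against 3 h and for the interactions), of which the text gives a part; the 5 with the smallest p where fewer than 3 passed; and from each list described up to 4 members with the smallest p and any that passed. A gene named in 1 comparison was given in others. Values of 4 genes are not reported here.

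Alternatives were normexp background correction (offset 50), quantile normalization, the percentile over probes detected on all arrays (21979), the deposited table, no filter on dim probes (31693 genes), only probes well above background on all 12 arrays (17786 genes), the mean over a gene's probes, a trend in the variance prior, mouse as a block, only the groups compared, each array left out, a fold of at least 1 on the log2 scale, and the estimated correlation. For LPS responses and interactions the mouse was a fixed block (4 residual degrees of freedom), and for genotype contrasts, where mice are nested, a random block with a consensus correlation of 0.101. The fit without the array with the most uneven spots was chosen after the data were seen. On data simulated without mouse differences, which favours mouse means, 100 of 22648 genes were changed by 1 or 2 (log2). The pipeline recovered 74% and 96% for untreated genotype (6 false calls) and 72% and 94% for LPS 3 h (10). The 3 h interaction gave 36% and 80% (5) and mouse means 86% and 100% (8).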

Results

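Gene expression was measured in macrophages grown from the bone marrow of 2 wildtype and 2 Commd1 knockout mice. COMMD1 is a subunit of the CCC complex, which sorts membrane proteins at endosomes, and it is also known to promote the turnover of the NF-kB subunit RelA and to take part in copper export. Marrow cells had been cultured for 10 days with 20 ng/ml GM-CSF, a growth factor for myeloid cells. The culture of each mouse was divided into an untreated sample and samples given 10 ng/mL lipopolysaccharide (LPS, the bacterial cell wall component sensed by the receptor TLR4) for 3 h or 24 h. The 12 samples formed 6 groups of 2, each sample on its own array.

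Of the probes on an array, 72.8% and 71.9% were well above background in the untreated wildtype samples and 69.2% and 65.7% in the untreated knockout samples. The values were 69.8% and 69.1% in wildtype and 64.0% and 66.4% in knockout after 3 h, and 67.9% and 65.1% in wildtype and 59.2% and 62.7% in knockout after 24 h. Levels across genes correlated with Pearson's r from 0.994 to 0.997 between the replicates of a group, where genes are not independent replicates. The number of arrays limits the precision. The first principal component held 46.7% of the variance and placed the untreated arrays between -96.8 and -92.7 and the 3 h arrays between 68.1 and 93.8. The second held 38.3% and placed the 24 h arrays between -102.9 and -78.5, below all other arrays. The third held 5.5% and separated the genotypes, with wildtype arrays between 16.9 and 34.8 and knockout arrays between -45.1 and -4.5.

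Commd1 was the targeted gene. Its probe (A_55_P2173098; mm9 chromosome 11, 22856412 to 22856471) gave log2 levels relative to the array's 75th percentile of 2.72 and 2.79 in the untreated wildtype samples, 2.73 and 2.70 after 3 h of LPS, and 2.89 and 2.85 after 24 h. At the same times levels were -0.50, -0.48 and -0.41 in knockout mouse 1 and -0.01, 0.07 and 0.06 in knockout mouse 2. Commd1 was 8.05-fold lower in untreated knockout than in untreated wildtype cells (-3.01 ± 0.23 on the log2 scale; SE, n = 2 per group; adjusted p = 0.00165). The difference was -2.92 ± 0.23 after 3 h (adjusted p = 0.0229) and -3.05 ± 0.23 after 24 h (adjusted p = 0.00509). Here arrays of a mouse counted as independent. Over mouse means adjusted p was 0.132, and with only the groups compared Commd1 passed at no time. The residual signal was well above background on every knockout array, and whether the probe lies in the deletion is not known. LPS did not change Commd1 measurably. Log2 values at 3 h and 24 h were -0.04 and 0.12 in wildtype cells (adjusted p = 0.908 and 0.705). In knockout cells they were 0.05 and 0.08 (0.872 and 0.795).

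**Figure D1:**
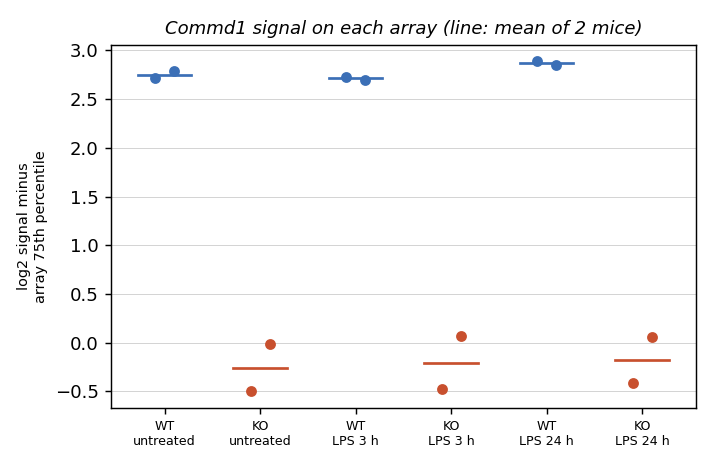
Commd1 level on each of the 12 arrays, as log2 signal relative to the array's 75th percentile, by genotype and time after LPS; points are mice and bars are group means. Wildtype arrays lay between 2.70 and 2.89 and knockout arrays between -0.50 and 0.07.

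Wildtype cells after 3 h of LPS were compared with untreated wildtype cells to describe the early response. Il6 was below background in untreated cells and rose at least 2230-fold, and Il1b, which encodes interleukin-1 beta, rose by 11.67 ± 0.35 on the log2 scale (SE, n = 2 per group). Il1a rose by 10.50 ± 0.18, Acod1, the enzyme that makes itaconate, by 11.22 ± 0.12, and Cxcl10, an interferon-induced chemokine, by 9.42 ± 0.16. Of genes without signal above background in untreated cells, Olr1, a scavenger receptor, rose at least 1070-fold, Cxcl3 at least 431-fold, Ifnb1, the interferon beta gene, at least 358-fold, Edn1 (endothelin-1) at least 357-fold, Il12b at least 347-fold and Ptgs2 (cyclooxygenase-2) at least 320-fold. The largest falls were in Fam214a at -6.81 ± 0.18, Sesn1, a stress-response gene, at -5.76 ± 0.17, Bmf, which promotes apoptosis, at -5.66 ± 0.36, the transcription factor Lyl1 at -5.21 ± 0.12 and the chemokine receptor Cxcr4 at -5.16 ± 0.23.

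All 22 inflammatory cytokines rose after 3 h in wildtype cells, with a median log2 change of 4.61, or 4.19 with members below background in 1 of the groups set to their bounds. Of 21 chemokines 19 rose, among them Ccl5 by 8.33 ± 0.21 and Cxcl2 by 6.62 ± 0.23, and 2 did not pass (median 4.13, or 3.56 with bounds). All 24 members of the NF-kB family and feedback list rose (median 3.48), including Cd40 by 7.55 ± 0.14, the inhibitor Nfkbia by 4.44 ± 0.11 and Tnfaip3, which encodes the feedback protein A20, by 5.59 ± 0.15. All 32 interferon-stimulated genes rose (median 4.42), including the antiviral genes Mx1 by 7.05 ± 0.13 and Ifit1 by 8.75 ± 0.17. Adjusted over the list alone the counts in these lists were the same 22, 19, 24 and 32. The camera test placed each of them above other genes, cytokines with adjusted p = 7.52e-16 (adjusted p = 0.0117 with an estimated correlation), chemokines with 4.77e-12 (adjusted p = 0.00701 with an estimated correlation), NF-kB genes with 2.08e-18 (adjusted p = 0.0676 with an estimated correlation) and interferon-stimulated genes with 1.18e-23 (adjusted p = 0.0797 with an estimated correlation).

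Antimicrobial and tissue effectors also rose after 3 h in wildtype cells, 22 of 27 over all genes and 23 adjusted over the list alone, with Cfb (complement factor B) up by 8.31 ± 0.21 and Nos2, the inducible nitric oxide synthase, by 4.49 ± 0.09. The list median was 3.20 (adjusted p = 2.46e-13, or adjusted p = 0.0676 with an estimated correlation). Of 22 immediate early and MAPK feedback genes 14 rose and 3 fell, with the same counts adjusted over the list alone, and the phosphatase gene Dusp2 rose by 5.97 ± 0.19. Their median change was 0.97 (adjusted p = 0.00583, or adjusted p = 0.355 with an estimated correlation). Of 15 MHC class II and costimulation genes 7 rose and 1 fell on both counts (over all genes and over the list alone), with Cd83 up by 3.74 ± 0.10 and Icosl by 3.34 ± 0.09. Over the list the median was 0.80 (adjusted p = 0.0274, or adjusted p = 0.609 with an estimated correlation). Of 19 copper homeostasis genes 10 rose and 1 fell on both counts, with Slc31a2 up by 1.55 ± 0.11 and Cp, the copper-carrying ferroxidase ceruloplasmin, by 4.57 ± 0.30. As a group they had a median of 0.44 (adjusted p = 0.0134, or adjusted p = 0.597 with an estimated correlation). Of 25 hypoxia-inducible genes 13 rose and 3 fell, 14 and 3 adjusted over the list alone, with the glycolytic genes Hk2 up by 3.36 ± 0.19 and Pfkfb3 by 3.00 ± 0.21. These genes had a median change of 0.32 (adjusted p = 0.0166, or adjusted p = 0.224 with an estimated correlation). The last call was lost when limma was fitted to the compared groups alone (adjusted p = 0.0666).

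Over all 22967 genes with a value, 10703 passed after 3 h in wildtype cells, 5338 higher and 5365 lower (49.9% higher), and 4245 of them changed at least 2-fold. Scaling on probes detected on all arrays moved the median of all genes from 0.03 to -0.09 and the split to 4216 higher and 6596 lower (39.0% higher). Each time was hybridized on a slide of its own, so LPS and slide cannot be told apart.

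After 24 h in wildtype cells Cfb rose relative to untreated cells by 11.83 ± 0.21 on the log2 scale (SE, n = 2 per group), Saa3, an acute-phase protein, by 11.06 ± 0.27, Acod1 by 10.78 ± 0.12, the chemokine genes Cxcl9 by 10.32 ± 0.76 and Ccl5 by 8.64 ± 0.21, and C3, the central complement component, by 7.08 ± 0.17. Ifnb1 rose at least 305-fold, Slfn1 at least 226-fold, Il23r at least 162-fold and Rasgrp1 at least 132-fold from below background. The transporter gene Slco2b1 fell at least 153-fold, and Gpr34, a receptor of macrophages and microglia, fell by 6.09 ± 0.19.

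All 32 interferon-stimulated genes rose at 24 h in wildtype cells, among them Oasl1 by 7.75 ± 0.12 and Isg20 by 7.05 ± 0.14. The group's median lay at 5.17 (adjusted p = 5.87e-27, or adjusted p = 0.0872 with an estimated correlation). Cytokines rose in 18 of 22 and 19 adjusted over the list alone, with Il10 up by 3.76 ± 0.17 and the interleukin-1 antagonist Il1rn by 5.64 ± 0.26. Together they gave a median of 1.80, or 1.38 with bounds (adjusted p = 4.7e-10, or adjusted p = 0.0409 with an estimated correlation). Of 21 chemokines 15 rose and 1 fell on both counts. The members' median was 1.73, or 1.66 with bounds (adjusted p = 1.45e-06, or adjusted p = 0.0406 with an estimated correlation). Of 24 NF-kB genes 20 rose on both counts, with Traf1 up by 3.32 ± 0.12. In this list the median was 1.38 (adjusted p = 4.7e-10, or adjusted p = 0.197 with an estimated correlation). Effectors rose in 22 and fell in 3 of 27 on both counts, with the histamine-forming enzyme Hdc up by 6.49 ± 0.20. Taking all members, the median was 2.61, or 2.17 with bounds (adjusted p = 1.84e-10, or adjusted p = 0.0872 with an estimated correlation). Of 15 MHC class II and costimulation genes 9 rose and 2 fell on both counts, with Cd86 up by 2.40 ± 0.20. The list median was 1.18 (adjusted p = 0.0274, or adjusted p = 0.745 with an estimated correlation). Macrophage markers rose in 10 and fell in 1 of 17, 10 and 2 adjusted over the list alone, with the Fc receptor Fcgr1 up by 3.37 ± 0.14 and Siglec1 by 3.45 ± 0.15. Their median change was 0.43 (adjusted p = 0.00763, or adjusted p = 0.745 with an estimated correlation).

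Cell-cycle and cholesterol genes fell at 24 h in wildtype cells. Of 26 proliferation genes 14 fell and 2 rose on both counts, and the mitotic genes Cdc20 fell by 4.14 ± 0.23 and Ccnb2 fell by 3.56 ± 0.26, while Tyms, the thymidylate synthase gene, rose by 2.34 ± 0.13. Over the list the median was -1.57 (adjusted p = 0.00564, or adjusted p = 0.862 with an estimated correlation). Of 20 cholesterol synthesis and uptake genes 16 fell and 1 rose on both counts, with Cyp51 at -1.82 ± 0.18. As a group they had a median of -1.13 (adjusted p = 0.000432, or adjusted p = 0.745 with an estimated correlation). Over all genes 11479 passed, 5422 higher and 6057 lower (47.2% higher), 4070 of them at least 2-fold. With normexp background correction the median of all genes moved from -0.04 to 0.18, the split became 9330 higher and 5146 lower (64.5% higher), and the calls of the MHC class II and costimulation list (adjusted p = 0.205) and of the macrophage markers (adjusted p = 0.227) were lost. The first of these was also lost with the mean over a gene's probes (adjusted p = 0.0941) and the second with quantile normalization (adjusted p = 0.147).

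Wildtype 24 h and 3 h samples were compared to separate early from late changes. Il6 fell by 7.45 ± 0.20 between 3 h and 24 h on the log2 scale (SE, n = 2 per group) and Il1b fell by 6.20 ± 0.35, Olr1 fell at least 736-fold and Cxcl3 at least 282-fold to below background. Adamts4, a protease of the extracellular matrix, fell by 8.86 ± 0.16. Ly6a, which encodes the interferon-responsive surface protein Sca-1, rose by 6.88 ± 0.22, and Il12rb1, a subunit of the interleukin-12 receptor, rose by 5.33 ± 0.13. Siglec1 rose by 3.52 ± 0.15.

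By list, 16 of 22 cytokines fell and 2 rose from 3 h to 24 h on both counts (median -3.05, or -2.82 with bounds, adjusted p = 2.97e-06, or adjusted p = 0.225 with an estimated correlation), and 22 of 24 NF-kB genes fell and 1 rose on both counts, with Cd40 at -4.25 ± 0.14 (median -2.09, adjusted p = 1.87e-10, or adjusted p = 0.225 with an estimated correlation). Of 21 chemokines 12 fell and 2 rose on both counts. These genes had a median change of -0.98 (adjusted p = 0.014, or adjusted p = 0.225 with an estimated correlation). Of 22 immediate early genes 11 fell and 2 rose on both counts, with Dusp2 at -6.39 ± 0.19. The group's median lay at -0.81 (adjusted p = 0.0225, or adjusted p = 0.565 with an estimated correlation). Of 25 hypoxia-inducible genes 14 fell and 2 rose, 15 and 2 adjusted over the list alone, with Ndrg1 at -3.98 ± 0.08. Together they gave a median of -0.49, or -0.45 with bounds (adjusted p = 0.0108, or adjusted p = 0.225 with an estimated correlation). Of 20 cholesterol genes 13 fell and 1 rose on both counts, with Cyp51 at -2.36 ± 0.18. The members' median was -0.93 (adjusted p = 0.00403, or adjusted p = 0.698 with an estimated correlation). Interferon-stimulated genes went both ways, 18 up and 7 down of 32, 19 and 7 adjusted over the list alone, with Irf7 at 3.42 ± 0.20 and Gbp5 at -2.05 ± 0.16. In this list the median was 0.60 (adjusted p = 0.0308, or adjusted p = 0.882 with an estimated correlation). Macrophage markers rose in 12 and fell in 3 of 17 on both counts. Taking all members, the median was 0.47 (adjusted p = 0.0184, or adjusted p = 0.668 with an estimated correlation).

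Over all genes 12081 differed between 24 h and 3 h, 5909 higher and 6172 lower (48.9% higher), 4614 of them at least 2-fold. With normexp background correction the median of all genes became 0.14, the split became 7785 higher and 5212 lower (59.9% higher), and the calls of the interferon-stimulated genes (adjusted p = 0.167) and macrophage markers (adjusted p = 0.0852) were lost. With only probes well above background on all arrays the calls of chemokines (adjusted p = 0.202) and interferon-stimulated genes (adjusted p = 0.0671) were lost.

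In knockout cells after 3 h of LPS Il6 rose at least 1850-fold and Ifnb1 at least 328-fold from below background, and Il12b rose at least 224-fold. Acod1 rose by 10.31 ± 0.12 on the log2 scale (SE, n = 2 per group), Il1b by 7.65 ± 0.35, Tnf by 8.65 ± 0.26 and Cxcl10 by 7.25 ± 0.16. Adamts4 rose by 9.63 ± 0.16. Bmf fell by 7.30 ± 0.36, and Fam214a stood at -7.17 ± 0.18, Sesn1 at -6.61 ± 0.17 and Cxcr4 at -5.56 ± 0.23. Over all genes 11974 passed, 6066 higher and 5908 lower (50.7% higher), 5365 of them at least 2-fold. Scaling on probes detected on all arrays moved the median of all genes from 0.06 to -0.09 and the split to 4680 higher and 7402 lower (38.7% higher), and quantile normalization moved that median to -0.07.

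The knockout response at 3 h was tested with the same lists. The MHC class II and costimulation list was not called, with 6 up and 2 down of 15, 7 and 2 adjusted over the list alone (median 0.33, adjusted p = 0.135). All 22 cytokines (median 4.36, or 4.13 with bounds, adjusted p = 8.01e-14, or adjusted p = 0.017 with an estimated correlation), all 24 NF-kB genes (median 3.25, adjusted p = 1.67e-15, or adjusted p = 0.0988 with an estimated correlation) and all 32 interferon-stimulated genes (median 3.82, adjusted p = 1.78e-19, or adjusted p = 0.119 with an estimated correlation) rose on both counts. Of 21 chemokines 19 rose, 20 adjusted over the list alone. The list median was 5.14, or 4.60 with bounds (adjusted p = 3.07e-10, or adjusted p = 0.0113 with an estimated correlation). Of 27 effectors 23 rose on both counts, with the collagenase gene Mmp13 up by 8.18 ± 0.13. Their median change was 3.58 (adjusted p = 1.5e-11, or adjusted p = 0.0988 with an estimated correlation). Of 22 immediate early genes 17 rose and 1 fell, 18 and 1 adjusted over the list alone, with Dusp1 up by 3.41 ± 0.11. Over the list the median was 1.39 (adjusted p = 1.32e-05, or adjusted p = 0.12 with an estimated correlation). Of 19 copper genes 11 rose and 1 fell, 12 and 1 adjusted over the list alone. As a group they had a median of 0.34 (adjusted p = 0.0176, or adjusted p = 0.49 with an estimated correlation). This call was lost with normexp background correction (adjusted p = 0.0534). Of 25 hypoxia-inducible genes 13 rose and 5 fell, 14 and 5 adjusted over the list alone. These genes had a median change of 0.30 (adjusted p = 0.0248, or adjusted p = 0.225 with an estimated correlation). This call was lost without the replicate 2 array of the knockout 3 h group (adjusted p = 0.0888), in the deposited table (adjusted p = 0.0548) and with only the compared groups (adjusted p = 0.121). Of 14 dendritic cell markers 9 rose and 1 fell on both counts, with the transcription factor Zbtb46 up by 6.24 ± 0.18. The group's median lay at 0.47 (adjusted p = 0.0471, or adjusted p = 0.348 with an estimated correlation). This call was lost without replicate 2 of the untreated knockout group (adjusted p = 0.117) and of the knockout 3 h group (adjusted p = 0.0608), with normexp background correction (adjusted p = 0.0739), in the deposited table (adjusted p = 0.0672) and in 4 other settings.

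In knockout cells after 24 h Saa3 rose by 10.39 ± 0.27 on the log2 scale (SE, n = 2 per group), Cfb by 9.98 ± 0.21, Acod1 by 9.73 ± 0.12 and Cxcl9 by 11.36 ± 0.76, and Ifnb1 rose at least 419-fold from below background. Slco2b1 fell at least 278-fold, Gpr34 fell by 6.87 ± 0.19 and Aspm, a gene of the mitotic spindle, fell by 6.16 ± 0.25. Il1b stood 0.78 ± 0.35 above the untreated knockout level, which did not pass (adjusted p = 0.0896). Over all genes 13223 passed, 5982 higher and 7241 lower (45.2% higher), 5276 of them at least 2-fold. With normexp background correction the median of all genes moved from -0.07 to 0.22 and the split to 10297 higher and 5634 lower (64.6% higher), and scaling on probes detected on all arrays moved that median to -0.19.

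All 32 interferon-stimulated genes rose at 24 h in knockout cells on both counts, Mx1 by 6.11 ± 0.13. Together they gave a median of 4.49 (adjusted p = 9.68e-23, or adjusted p = 0.12 with an estimated correlation). Cytokines rose in 17 of 22, 18 adjusted over the list alone. The members' median was 1.47, or 1.45 with bounds (adjusted p = 4.73e-08, or adjusted p = 0.111 with an estimated correlation). Of 21 chemokines 12 rose and 3 fell, 13 and 3 adjusted over the list alone. In this list the median was 1.23 (adjusted p = 0.00162, or adjusted p = 0.111 with an estimated correlation). Of 24 NF-kB genes 19 rose and 1 fell, 20 and 1 adjusted over the list alone. Taking all members, the median was 0.94 (adjusted p = 5.02e-07, or adjusted p = 0.316 with an estimated correlation). Effectors rose in 20 and fell in 1 of 27 on both counts. The list median was 2.77, or 1.96 with bounds (adjusted p = 5.06e-09, or adjusted p = 0.12 with an estimated correlation). Of 20 cholesterol genes 13 fell and 1 rose, 14 and 1 adjusted over the list alone. Their median change was -1.01 (adjusted p = 0.0082, or adjusted p = 0.72 with an estimated correlation). Of 26 proliferation genes 14 fell and 4 rose, 15 and 4 adjusted over the list alone, with Cdc20 at -5.25 ± 0.23. Over the list the median was -1.68 (adjusted p = 0.0385, or adjusted p = 0.72 with an estimated correlation). This call was lost without the replicate 2 array of the untreated knockout group (adjusted p = 0.129) and without the replicate 1 array of the knockout 24 h group (adjusted p = 0.0576), and with scaling on probes detected on all arrays (adjusted p = 0.0957) or only the compared groups (adjusted p = 0.0528). Lysosome and phagocytosis genes rose in 13 and fell in 3 of 22 on both counts, with the scavenger receptor Msr1 up by 3.36 ± 0.18. As a group they had a median of 0.32 (adjusted p = 0.0232, or adjusted p = 0.229 with an estimated correlation). This call was lost with normexp background correction (adjusted p = 0.651), with quantile normalization (adjusted p = 0.76), without the filter on dim probes (adjusted p = 0.0543), with only probes well above background on all arrays (adjusted p = 0.0564) and without the replicate 1 array of the untreated knockout group (adjusted p = 0.051).

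The LPS responses of the genotypes, which share no arrays but the same slide at each time, were set side by side across genes. Any difference between slides is common to both responses and would add to their agreement. At 3 h the log2 changes of 22966 genes correlated with Pearson's r of 0.936 and Spearman's rho of 0.883, where genes are not independent replicates. In both genotypes 4578 genes rose and 4755 fell, where independent calls give 1410 and 1380, and 17 genes moved in opposite directions. At 24 h the correlation over 22964 genes was 0.915 and rho was 0.875, with 4679 genes up and 5419 down in both, where independent calls give 1412 and 1910, and 18 in opposite directions.

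Untreated knockout and wildtype cells were compared to ask which genes differ before LPS is added. Il1b was 18.2-fold higher in knockout cells (4.19 ± 0.35 on the log2 scale; SE, n = 2 per group; adjusted p = 0.00222), Cxcl10 was higher by 2.40 ± 0.16 (adjusted p = 0.00148), C3 by 2.07 ± 0.17, Cfb by 1.69 ± 0.21 and Ccl5 by 1.65 ± 0.21. Kmo, an enzyme of tryptophan breakdown, was higher by 2.03 ± 0.20, and Jaml, an adhesion molecule, by 3.48 ± 0.34. Lower in knockout cells were Cd200, the ligand of an inhibitory receptor of myeloid cells, at -2.54 ± 0.16 (adjusted p = 0.00148), the transcription factor Egr2 at -2.11 ± 0.16 (adjusted p = 0.00161), the MAP kinase phosphatase Dusp4 at -2.17 ± 0.23, the lipid-binding protein Fabp7 at -2.63 ± 0.24 and the secreted protease Adamts1 at -2.61 ± 0.19. The interleukin-1 antagonist Il1rn was at -1.65 ± 0.26 (adjusted p = 0.0157). Tnf stood at -0.82 ± 0.26 and did not pass (adjusted p = 0.102), and Il6 was below background in both groups.

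**Figure D2:**
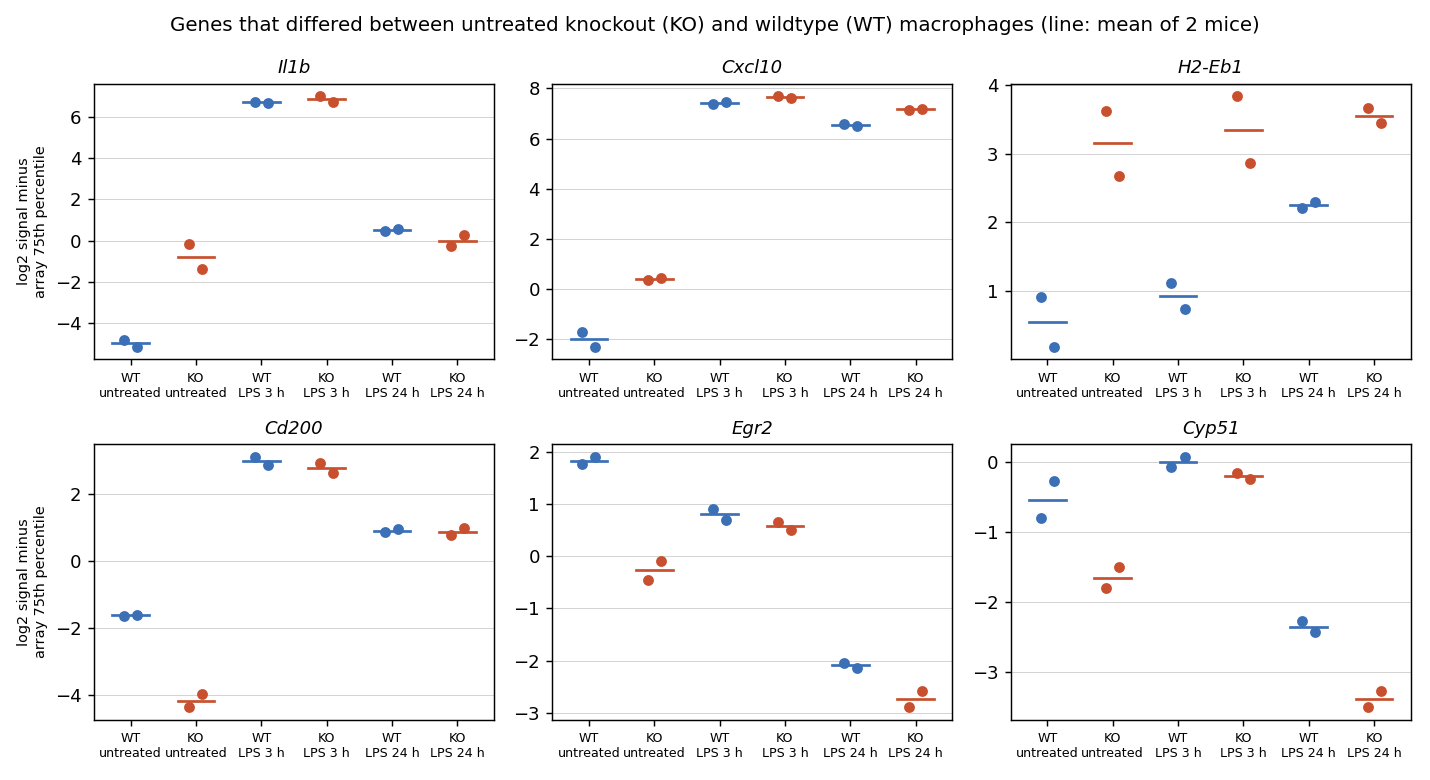
Levels of Il1b, Cxcl10, H2-Eb1, Cd200, Egr2 and Cyp51 on each array, as log2 signal relative to the array's 75th percentile, by genotype and time after LPS; points are mice and bars are group means. Mean Il1b was -4.97 in wildtype and -0.78 in knockout cells before LPS and 6.70 and 6.87 after 3 h.

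Of 32 interferon-stimulated genes 18 rose in untreated knockout relative to wildtype cells and none fell, and 30 rose adjusted over the list alone, with Gbp5 at 1.79 ± 0.16, Ifit1 at 1.48 ± 0.17 and Mx1 at 1.28 ± 0.13. These genes had a median change of 0.66 (adjusted p = 5.45e-18, or adjusted p = 0.17 with an estimated correlation). Of 15 MHC class II and costimulation genes 10 rose, 11 adjusted over the list alone, with the class II chain H2-Eb1 at 2.60 ± 0.40, the invariant chain Cd74 at 2.27 ± 0.30, H2-Oa at 1.39 ± 0.12 and Icosl at 0.80 ± 0.09. The group's median lay at 0.80 (adjusted p = 9.46e-09, or adjusted p = 0.17 with an estimated correlation). Of 24 NF-kB genes 6 rose, 9 adjusted over the list alone, with Relb at 0.94 ± 0.12 and Nfkbia at 0.84 ± 0.11. Together they gave a median of 0.23 (adjusted p = 0.00509, or adjusted p = 0.477 with an estimated correlation). Of 17 macrophage markers 3 rose, and 8 rose and 1 fell adjusted over the list alone, with the complement component C1qb at 0.48 ± 0.09 and Fcgr1 at 0.60 ± 0.14. The members' median was 0.30 (adjusted p = 0.00372, or adjusted p = 0.475 with an estimated correlation).

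Of 20 cholesterol synthesis and uptake genes 10 fell and none rose in untreated knockout relative to wildtype cells, and 14 fell adjusted over the list alone, with Cyp51 at -1.12 ± 0.18 and Hmgcs1 at -0.62 ± 0.12. In this list the median was -0.62 (adjusted p = 3.9e-10, or adjusted p = 0.252 with an estimated correlation). Of 22 immediate early genes 6 fell and 2 rose, 10 and 4 adjusted over the list alone, with Egr1 at -1.49 ± 0.25 and Ier3, an antiapoptotic early gene, at 1.79 ± 0.20. Taking all members, the median was -0.28 (adjusted p = 0.00803, or adjusted p = 0.321 with an estimated correlation). Of 25 hypoxia-inducible genes 3 fell on both counts, with the glucose transporter Slc2a1 at -0.79 ± 0.12. The list median was -0.22 (adjusted p = 0.00372, or adjusted p = 0.17 with an estimated correlation). Of 26 proliferation genes 1 fell, Pcna at -1.23 ± 0.23, and 3 fell adjusted over the list alone. Their median change was -0.43 (adjusted p = 6.61e-06, or adjusted p = 0.477 with an estimated correlation). Of 18 unfolded protein response genes 2 fell and 1 rose, 5 and 1 adjusted over the list alone, with Atf4 at -0.55 ± 0.11 and Herpud1 at 0.63 ± 0.13. Over the list the median was -0.23 (adjusted p = 0.000583, or adjusted p = 0.282 with an estimated correlation). Of 20 NRF2 and oxidative stress genes 2 fell and 1 rose, 5 and 1 adjusted over the list alone, with Srxn1 at -0.46 ± 0.10. As a group they had a median of -0.20 (adjusted p = 0.0317, or adjusted p = 0.477 with an estimated correlation). Of 11 heat shock genes Hsp90aa1 fell, by 0.69 ± 0.11, and 2 fell adjusted over the list alone. These genes had a median change of -0.17 (adjusted p = 0.00968, or adjusted p = 0.235 with an estimated correlation). Of 11 osteoclast markers 2 fell, 4 adjusted over the list alone, with the protease Ctsk at -1.02 ± 0.09. The group's median lay at -0.60, or -0.42 with bounds (adjusted p = 0.00372, or adjusted p = 0.17 with an estimated correlation). Of 8 markers of mast cells, basophils and eosinophils 3 fell on both counts, with the eosinophil lectin Siglecf at -0.79 ± 0.10. Together they gave a median of -0.49, or -0.17 with bounds (adjusted p = 0.00861, or adjusted p = 0.17 with an estimated correlation).

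The other lists were not placed above or below other genes in untreated cells. Of 22 cytokines 4 rose and 1 fell, 7 and 3 adjusted over the list alone (median 0.32, or 0.00 with bounds, adjusted p = 0.197), and of 21 chemokines 6 rose and 4 fell, 7 and 4 adjusted over the list alone (median 0.30, or 0.00 with bounds, adjusted p = 0.144), where Ccl3 was at -1.33 ± 0.22 and Ccl4 at -1.73 ± 0.25. Effectors rose in 7 and fell in 4 of 27, 10 and 7 adjusted over the list alone (median 0.13, or 0.00 with bounds, adjusted p = 0.481), and alternative activation genes rose in 4 and fell in 2 of 15, 7 and 3 adjusted over the list alone (median 0.24, or 0.01 with bounds, adjusted p = 0.197). Copper homeostasis genes split into 1 up, Cp at 2.62 ± 0.30, and 1 down, the metalloreductase Steap3 at -0.63 ± 0.11, of 19 on both counts. The members' median was 0.01, or 0.00 with bounds (adjusted p = 0.848). None of the 19 other members of the COMMD family and the CCC or retriever complexes passed on either count. In this list the median was -0.06 (adjusted p = 0.144). Oxidative phosphorylation genes had 1 of 25 lower on both counts (median -0.06, adjusted p = 0.105). Lysosome genes had 1 higher and 4 lower of 22, 2 and 4 adjusted over the list alone, with a median of 0.01, a mean of -0.16 and a test direction of down (adjusted p = 0.197).

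Among markers of other cell types in untreated cells, dendritic cell markers had 1 higher and 1 lower of 14 on both counts (median 0.08, or 0.03 with bounds, adjusted p = 0.833), neutrophil markers 0 of 11 (median -0.33, adjusted p = 0.197), B cell markers 1 higher of 11 on both counts (median 0.16, adjusted p = 0.197) and T and NK cell markers 0 of 14, with a median of -0.04, or -0.01 with bounds, a mean of 0.09 and a test direction of up (adjusted p = 0.737). Erythroid markers had 1 higher of 6 on both counts (median 0.05, adjusted p = 0.287), megakaryocyte and platelet markers 1 higher of 8 on both counts, Ppbp at 1.66 ± 0.16 (median 0.09, adjusted p = 0.931), and stroma markers 2 higher of 16, 3 adjusted over the list alone (median 0.21, adjusted p = 0.0668).

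Over all genes 1570 differed between untreated knockout and wildtype cells, 865 higher and 705 lower (55.1% higher), 537 of them at least 2-fold. This count was 618 and 182 without the untreated wildtype arrays of replicate 1 and 2 in turn (in the latter 69 higher and 113 lower, 37.9% higher) and 154 without replicate 1 of the untreated knockout group, 453 without the filter on dim probes, 2576 with normexp background correction, 2368 with a trend in the variance prior, and, in limma fitted to these 4 arrays alone, 0 with 5158 at unadjusted p under 0.05. Of the 42 named genes that passed, 22 also passed without each of these arrays in turn, among them Il1b, Cxcl10, C3, Cfb, Ccl5, Gbp5, Mx1, H2-Oa, Cd200 and Egr2. Without wildtype replicate 2 and without knockout replicate 1 in turn 19 missed the threshold (adjusted p up to 0.217 and 0.256), H2-Eb1, Cd74, Nfkbia, Cyp51 and Egr1 among them, as did the NRF2 list (adjusted p = 0.0718 and 0.1), and 7 and 3 missed it without wildtype replicate 1 and knockout replicate 2 (adjusted p up to 0.114 and 0.0737). The mast cell list lost its call without the filter on dim probes (adjusted p = 0.0815), and the immediate early list with these arrays alone (adjusted p = 0.0621).

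**Figure D3:**
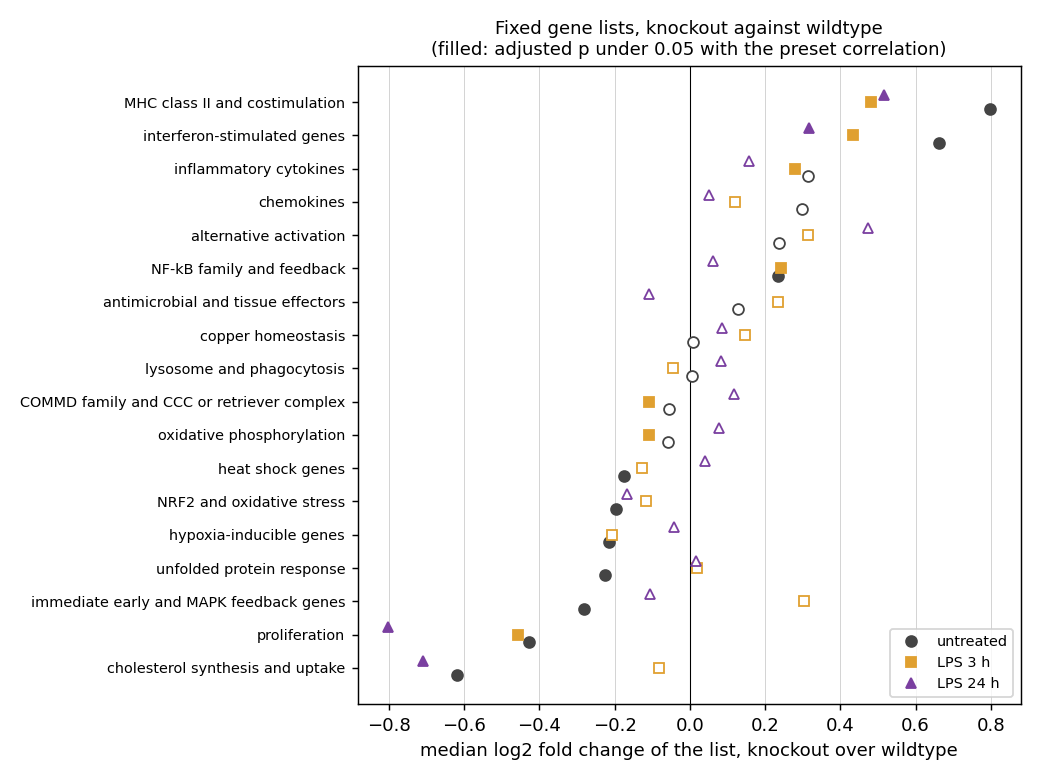
Median log2 fold change between knockout and wildtype cells of the members of each of 18 gene lists that are not cell type markers, untreated and after 3 h and 24 h of LPS; filled points mark lists with an adjusted p under 0.05 in the camera test with the preset correlation. The interferon-stimulated genes lay at 0.66, 0.43 and 0.32 and the cholesterol genes at -0.62 before LPS and -0.71 after 24 h.

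After 3 h of LPS knockout and wildtype cells still differed in antigen-presentation genes. The adhesion receptor Adgre4 was higher in knockout cells by 3.68 ± 0.66 on the log2 scale (SE, n = 2 per group), H2-Eb1 by 2.43 ± 0.40, H2-Aa by 2.30 ± 0.38, Cd74 by 1.91 ± 0.30 and the platelet adhesion molecule Selp by 1.81 ± 0.23. Csf3, which encodes the growth factor G-CSF, was at least 2.21-fold higher. Cgn, a tight junction protein, was lower at -1.74 ± 0.17 and Ctsk at -0.87 ± 0.09. Genes that did not pass between genotypes at 3 h were Tnf at 0.10 (adjusted p = 0.85), Il6 at 0.22 ± 0.20 (adjusted p = 0.527), Il12b at -0.15 (adjusted p = 0.808), Il1b at 0.17 ± 0.35 (adjusted p = 0.812) and Cxcl10 at 0.23 (adjusted p = 0.418).

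Of 32 interferon-stimulated genes 2 rose at 3 h in knockout relative to wildtype cells, Oas2 at 0.84 ± 0.13 and the helicase Dhx58 at 0.68 ± 0.12, and 14 rose adjusted over the list alone (median 0.43, adjusted p = 3.13e-09), and of 15 MHC class II and costimulation genes 7 rose, 8 adjusted over the list alone (median 0.48, adjusted p = 4.86e-06). Of 22 cytokines 2 rose, and 9 rose and 1 fell adjusted over the list alone (median 0.28, adjusted p = 0.0148). None of 24 NF-kB genes passed over all genes and 2 rose adjusted over the list alone (median 0.24, adjusted p = 0.000274). Macrophage markers had 1 higher, Maf at 0.66 ± 0.12, and 1 lower, the lysozyme gene Lyz2 at -0.63 ± 0.12, of 17, and 6 and 1 adjusted over the list alone. Taking all members, the median was 0.25 (adjusted p = 0.00345). For all 5 of these lists adjusted p = 0.528 with an estimated correlation. Lower lists were proliferation (0 of 26 passed on either count; median -0.46; adjusted p = 0.000419), oxidative phosphorylation (0 of 25; median -0.11; adjusted p = 0.0083) and COMMD and CCC complex genes (0 of 19, 2 lower adjusted over the list alone; median -0.11; adjusted p = 0.0347), each with adjusted p = 0.544 with an estimated correlation. Leaving out replicate 1 of the knockout 3 h group took the proliferation list to a median of -0.11 (adjusted p = 0.256) and the COMMD list to adjusted p = 0.156, leaving out wildtype replicate 2 took the COMMD list to adjusted p = 0.05 and fitting only these 4 arrays to adjusted p = 0.0507, and the cytokine call was lost with normexp background correction (adjusted p = 0.0928).

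Over all genes 387 differed between genotypes at 3 h, 245 higher and 142 lower (63.3% higher), 108 of them at least 2-fold, and scaling on probes detected on all arrays gave 255 higher and 323 lower (44.1% higher). The count was 26 and 51 without the wildtype 3 h arrays of replicate 1 and 2 in turn, where the split turned to 3 higher and 23 lower (11.5% higher) and to 12 and 39 (23.5% higher). It was 22 and 2930 without those of the knockout, and in limma fitted to these 4 arrays alone 0, with 4349 at unadjusted p under 0.05. Of the 13 named genes that passed, 12 and 10 missed the threshold without wildtype replicate 1 and 2 in turn (adjusted p up to 0.229 and 0.196) and 10 without knockout replicate 1 (up to 0.193), while Commd1 passed in each of these fits. Without the filter on dim probes limma called 0 genes, with 6056 at unadjusted p under 0.05, and the count was 1739 with normexp background correction, 815 in the deposited table, 1469 with only probes well above background on all arrays and 1352 with a trend in the variance prior.

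After 24 h of LPS Gpr171 was higher in knockout cells by 1.81 ± 0.29 on the log2 scale (SE, n = 2 per group), the phospholipid transfer protein gene Pltp by 1.72 ± 0.30 and Il4ra, the interleukin-4 receptor, by 1.51 ± 0.26. Nos2 was higher by 0.67 ± 0.09 and Dusp2 by 1.18 ± 0.19. The scavenger receptor Marco was lower at -2.07 ± 0.24, Lyz2 at -1.13 ± 0.12 and the neutrophil-attracting chemokine Cxcl2 at -1.70 ± 0.23, and Cxcl1 was at least 1.48-fold lower. Il6 at 0.43 ± 0.20 (adjusted p = 0.251), Tnf at -0.42 (adjusted p = 0.389), Il1b at -0.50 ± 0.35 (adjusted p = 0.448) and H2-Eb1 at 1.30 ± 0.40 (adjusted p = 0.12) did not pass.

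Of 20 cholesterol genes 5 fell at 24 h in knockout relative to wildtype cells, and 12 fell and 1 rose adjusted over the list alone, with Sqle at -1.31 ± 0.20 and Cyp51 at -1.03 ± 0.18. The list median was -0.71 (adjusted p = 1.7e-07, or adjusted p = 0.696 with an estimated correlation). No proliferation gene of 26 passed over all genes and 11 fell adjusted over the list alone. Their median change was -0.80 (adjusted p = 1.92e-07, or adjusted p = 0.774 with an estimated correlation). No interferon-stimulated gene of 32 passed over all genes and 3 rose adjusted over the list alone (median 0.32, adjusted p = 3.54e-08, or adjusted p = 0.696 with an estimated correlation), and no MHC class II and costimulation gene of 15 passed over all genes and 9 rose adjusted over the list alone (median 0.52, adjusted p = 1.92e-05, or adjusted p = 0.696 with an estimated correlation). Over all genes 549 differed, 165 higher and 384 lower (30.1% higher), 169 of them at least 2-fold, against 322 higher and 340 lower (48.6% higher) with normexp background correction. The count was 60 and 88 without the wildtype 24 h arrays of replicate 1 and 2 in turn, 103 without the filter on dim probes, 845 with scaling on probes detected on all arrays, 947 with only probes well above background on all arrays, 1046 with a trend in the variance prior and, in limma fitted to these 4 arrays alone, 0 with 4284 at unadjusted p under 0.05. Of the 12 named genes that passed, 11 and 10 missed the threshold without wildtype replicate 1 and 2 in turn (adjusted p up to 0.182 and 0.146) and 6 and 2 without knockout replicate 1 and 2 (up to 0.0793 and 0.0597), while Commd1 passed in each of these fits.

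For the genotype difference over all times the 3 arrays of each mouse were averaged, so that 2 mice were compared with 2. The genes with the smallest p were Adamts1 at -1.48 ± 0.08 on the log2 scale (SE, n = 2 mice per genotype), Lncenc1 at 1.13 ± 0.07, Dach1 at -1.56 ± 0.10, Chsy3 at -1.05 ± 0.07 and Commd1 at -2.99 ± 0.19, each with adjusted p = 0.132, and limma called 0 genes, with 5537 at unadjusted p under 0.05. With mouse as a random block over the 12 arrays 3613 genes passed, among them Commd1 (adjusted p = 0.000242), Dach1 (0.00116), Adamts1 (0.00219) and Chsy3 (0.0204), while Lncenc1 did not (0.159). In limma the count was 0 without wildtype mouse 1 (2590 at unadjusted p under 0.05), wildtype mouse 2 (2448) or knockout mouse 1 (4345), and it was 1456 without knockout mouse 2, 274 with normexp background correction and 63 with a trend in the variance prior.

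The difference of the LPS response between genotypes at 3 h was tested as an interaction term. Cxcl10 rose by 9.42 ± 0.16 in wildtype and by 7.25 ± 0.16 in knockout cells, a difference of -2.17 ± 0.23 on the log2 scale (SE, n = 2 per group). Mean Cxcl10 before LPS was -1.99 in wildtype and 0.40 in knockout cells, and at 3 h it was 7.42 and 7.65. Cd200 had a larger response in knockout cells by 2.31 ± 0.23, from means of -1.63 and -4.17 before LPS to 2.99 and 2.76 at 3 h, and Slamf8, a surface receptor of myeloid cells, by 1.27 ± 0.13. Npas4, an activity-dependent transcription factor, fell in wildtype cells from -2.32 to -4.76 and stood at -4.28 and -4.40 in knockout cells, a difference of 2.33 ± 0.25. These were 4 of the 8 genes that passed, each with adjusted p = 0.0317, 6 with a higher and 2 with a lower value of the difference; Sox7, Ttll2 and Vgll4 were below background in at least 1 of the groups. The difference for Il1b, -4.02 ± 0.50, did not pass (adjusted p = 0.0528).

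By list, the 3 h response of interferon-stimulated genes was smaller in knockout cells by the median (-0.31; adjusted p = 3.9e-05, or adjusted p = 0.694 with an estimated correlation), with 0 of 32 members passing and 5 lower adjusted over the list alone. Immediate early genes had a median difference of 0.66 with 0 of 22 passing, and 11 higher and 1 lower adjusted over the list alone (adjusted p = 6.04e-05, or adjusted p = 0.416 with an estimated correlation). Cholesterol genes had 0.66 with 0 of 20 passing and 8 higher adjusted over the list alone (adjusted p = 3.9e-05, or adjusted p = 0.694 with an estimated correlation). The list medians were 0.17 for the unfolded protein response (0 of 18 passing, 3 higher adjusted over the list alone; adjusted p = 0.00269, or adjusted p = 0.694 with an estimated correlation) and 0.65 for mast cell, basophil and eosinophil markers (0 of 8, 3 higher adjusted over the list alone; adjusted p = 0.00473, or adjusted p = 0.416 with an estimated correlation). Without replicate 2 of the knockout 3 h group the calls of interferon-stimulated genes and of the mast cell list (adjusted p = 0.0596) were lost, and the latter was also lost without the filter on dim probes (adjusted p = 0.109). Without that array the median of the interferon-stimulated genes was -0.13 (adjusted p = 0.0962).

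With mouse as a block, none of the 8 genes passed at 3 h, with adjusted p from 0.0809 for Vgll4 to 0.132 for Cxcl10, and limma called 1 other gene, Chac1 at 2.17 ± 0.36 without the block (adjusted p = 0.0497 with it), chosen here after its values were seen. In limma the count of 8 became 0 without replicate 1 of the untreated knockout group (1966 at unadjusted p under 0.05) or of the knockout 3 h group (2629), 0 without the filter on dim probes (2895) and 0 with only the 8 arrays compared (2860). It was 5 and 20 without the untreated wildtype arrays of replicate 1 and 2 in turn, 21 and 16 without the wildtype 3 h arrays (4 with a higher and 17 with a lower difference, and 4 and 12), 56 without replicate 2 of the untreated knockout group and 371 without replicate 2 of the knockout 3 h group. Of the 7 named genes that passed, 6 and 4 missed the threshold without the untreated wildtype arrays of replicate 1 and 2 in turn (adjusted p up to 0.0611 and 0.0735), and 3 and 5 without the wildtype 3 h arrays (up to 0.0607 and 0.0696). The count was 39 in the deposited table, 106 with normexp background correction, and 77 both with a trend in the variance prior and with only probes well above background on all arrays.

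At 24 h Il1b was well above background in all groups, and its LPS response differed between genotypes by -4.69 ± 0.50 on the log2 scale (SE, n = 2 per group; adjusted p = 0.0279), from means of -4.97 in wildtype and -0.78 in knockout cells before LPS to 0.50 and 0.00 at 24 h. Cxcl10 differed by -1.79 ± 0.23 (adjusted p = 0.0395), C3 by -1.90 ± 0.24 (adjusted p = 0.0395) and Ier3 by -1.88 ± 0.28 (adjusted p = 0.0488). Cd200 differed by 2.51 ± 0.23 (adjusted p = 0.0201), Dusp1 by 1.02 ± 0.15 (adjusted p = 0.0461), the stress-induced transcription factor Atf3 by 1.36 ± 0.20 (adjusted p = 0.0478) and Egr2 by 1.45 ± 0.22 (adjusted p = 0.0489). In all 75 genes passed, 35 with a higher and 40 with a lower value of the difference, 66 of them with a difference of at least 1 on the log2 scale. The split was 155 higher and 91 lower (63.0% higher) with normexp background correction and 110 and 71 (60.8% higher) in the deposited table. It was 55 and 96 (36.4% higher) with mouse as a block, 13 and 4 and then 19 and 5 without the untreated wildtype arrays of replicate 1 and 2 in turn, and 5 and 10 and then 11 and 28 without the wildtype 24 h arrays.

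For the 24 h difference 13 lists were called, and with an estimated correlation none was (lowest adjusted p = 0.37). Interferon-stimulated genes had a median difference of -0.39 (0 of 32 passing, 7 with a lower difference adjusted over the list alone; adjusted p = 6.01e-06, or adjusted p = 0.407 with an estimated correlation). MHC class II and costimulation genes had -0.69 (0 of 15 passing, 1 higher and 5 lower adjusted over the list alone; adjusted p = 0.00488, or adjusted p = 0.407 with an estimated correlation). For both lists the level itself was higher in knockout cells at 24 h by the median (0.32 and 0.52), and so it was before LPS (0.66 and 0.80). The median difference was -0.34 for macrophage markers (0 of 17, 3 lower; adjusted p = 0.00421, or adjusted p = 0.409 with an estimated correlation) and -0.31 for chemokines (2 of 21 lower, 4 higher and 8 lower adjusted over the list alone; adjusted p = 0.0411, or adjusted p = 0.37 with an estimated correlation). The chemokine call was lost with mouse as a block (adjusted p = 0.0528), with normexp background correction (0.0967), in the deposited table (median -0.12, adjusted p = 0.104), with only probes well above background on all arrays (0.21) and without either array of the knockout 24 h group in turn (0.0941 and 0.0677). Immediate early genes had a median difference of 0.33 (3 higher and 1 lower of 22, 9 and 3 adjusted over the list alone; adjusted p = 0.0129, or adjusted p = 0.407 with an estimated correlation), a call lost without replicate 2 of the untreated wildtype group (adjusted p = 0.0794) and without replicate 1 of the knockout 24 h group (adjusted p = 0.229). The other 8 lists had medians from 0.14 for lysosome and phagocytosis genes to 0.36 for mast cell, basophil and eosinophil markers.

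Most of these 24 h list calls depended on the setting. Of 19 settings, the estimated correlation among them, 13 ended the call of chemokines and 13 that of hypoxia-inducible genes, 10 that of mast cell, basophil and eosinophil markers, 6 that of osteoclast markers, and 4 each those of oxidative phosphorylation and heat shock genes. The calls of immediate early and lysosome genes were lost in 3 each, and that of COMMD and CCC genes in 2, among them the fit without replicate 2 of the knockout 24 h group (adjusted p = 0.0646). Those of interferon-stimulated genes, MHC class II and costimulation genes, macrophage markers and the unfolded protein response were lost in 1, the estimated correlation.

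With mouse as a block 151 genes passed at 24 h, and 5 of the 18 named genes that passed without it did not, among them Atf3 (adjusted p = 0.0543), Dusp1 (0.053) and Egr2 (0.0508). Of these 18, 13 and 13 missed the threshold without the untreated wildtype arrays of replicate 1 and 2 in turn (adjusted p up to 0.0944 and 0.138), 13 and 11 without the wildtype 24 h arrays (up to 0.134 and 0.141), 15 and 6 without the untreated knockout arrays (up to 0.14 and 0.0722) and 4 and 6 without the knockout 24 h arrays (up to 0.0566 and 0.0716). Il1b was among those that missed it without either untreated wildtype array and without replicate 1 of the wildtype 24 h group, and Cd200 without replicate 1 of the untreated knockout group (adjusted p = 0.0509). The count was 17 and 24 without the untreated wildtype arrays of replicate 1 and 2 in turn, 15 and 39 without the wildtype 24 h arrays, 4 without replicate 1 of the untreated knockout group, and 239 and 195 without the knockout 24 h arrays. It was 0 without the filter on dim probes, where limma gave 3396 genes at unadjusted p under 0.05, and 2 with only the 8 arrays compared (Prss46 and Ttll2, the first chosen here after its values were seen), 181 in the deposited table, 246 with normexp background correction, 278 with a trend in the variance prior and 242 with only probes well above background on all arrays.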

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

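Each value in this part came from a test of the difference of the LPS response between genotypes (an interaction term, knockout minus wildtype on the log2 scale), and no test was chosen after its result was seen. A value above or below 0 is a more positive or more negative change after LPS in knockout than in wildtype cells, not a higher or lower level.

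The response to LPS for 3 h differed between genotypes in 8 genes, and with mouse as a block none of them passed (adjusted p up to 0.132 for Cxcl10). The differences were 2.33 for Npas4, 2.31 for Cd200, 1.27 for Slamf8 and -2.17 for Cxcl10, which were well above background on both arrays of all groups. Sox7, Ttll2 and Vgll4 passed (adjusted p = 0.0317 each) but were not above background in every group compared, so none has a reliable size. By list the median differences were 0.66 for immediate early and MAPK feedback genes, 0.66 for cholesterol synthesis and uptake, 0.65 for mast cell, basophil and eosinophil markers, 0.17 for the unfolded protein response and -0.31 for interferon-stimulated genes. With an estimated correlation no list was called (lowest adjusted p = 0.416).

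The response to LPS for 24 h differed between genotypes in 75 genes, and in 151 with mouse as a block. The difference was 2.51 for Cd200 and -4.69 for Il1b, which were well above background on both arrays of all groups. Not above background in every group compared, and so given without a size, were Chsy3 (adjusted p = 0.0334), Ttll2 (0.0165), Acot4 (0.0446), Slc6a19 (0.0478), Vmn1r235 (0.0478), Ppm1n (0.0201), Hpgd (0.0395), Arg2 (0.0488) and Cxcl3 (0.0354). With mouse as a block Slc6a19 and Vmn1r235 did not pass.

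By list, the median 24 h differences above 0 were 0.36 for mast cell, basophil and eosinophil markers, 0.33 for immediate early and MAPK feedback genes, 0.25 for osteoclast markers, 0.24 for the unfolded protein response, 0.22 for heat shock genes, 0.18 for hypoxia-inducible genes, 0.17 for the COMMD family and the CCC or retriever complexes, 0.15 for oxidative phosphorylation and 0.14 for lysosome and phagocytosis. Those below 0 were -0.69 for MHC class II and costimulation, -0.39 for interferon-stimulated genes, -0.34 for macrophage markers and -0.31 for chemokines. With an estimated correlation none of these 13 lists was called (lowest adjusted p = 0.37), and most calls depended on the setting.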

How the results depend on the processing

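The fit without the most uneven array (replicate 1 of the knockout 24 h group) was chosen after results were seen. Of 228 values for named genes 126 kept direction and side of the threshold under every alternative run. No passing genotype or interaction value was among them. The 24 h difference for Cxcl3 alone lost its direction, from -1.92 (signals partly below background) to 0.00 in the deposited table with its floor. Of 86 list results 6 kept theirs under every alternative, and none reversed. The cause of the following differences was not tested except where fewer arrays or genes were fitted. With an estimated correlation 6 of the 86 list calls passed.

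Counts for knockout against wildtype at 0, 3 and 24 h, the 3 h and 24 h differences of response and the mean over times were, in that order, 1570, 387, 549, 8, 75 and 0. They became 2576, 1739, 662, 106, 246 and 274 with normexp, and 2368, 1352, 1046, 77, 278 and 63 with a variance trend. Without the filter they became 453, 0, 103, 0 and 0, and with only the groups compared 0, 0, 0, 0 and 2. Beside these zeros, limma gave at unadjusted p under 0.05, without the filter, 6056 at 3 h and 2895 and 3396 for the differences, and with only the groups compared 5158, 4349, 4284 and 2860. The deposited table gave 815 at 3 h and 39 and 181 for the differences. Probes above background on all arrays gave 1469 at 3 h, 947 at 24 h, and 77 and 242. The percentile over detected probes gave 845 at 24 h. The replicate block gave 1 and 151 for the differences and 3613 for the mean over times. The fit without the uneven array gave 903 at 3 h and 1 for the 3 h difference. A fold of at least 1 on the log2 scale left 4245, 4070, 4614, 5365 and 5276 genes for LPS and 537, 108 and 169 for genotype.

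With 1 array left out, the counts ran from 154 to 1295 (untreated), 22 to 2930 (3 h), 60 to 791 (24 h), and 0 to 371 and 4 to 239 (differences), and with 1 mouse left out 0 to 1456 (mean over times). The agreement of the LPS responses (0.936 and 0.915) ran from 0.917 to 0.936 and 0.891 to 0.918; it was 0.955 and 0.943 with normexp, 0.861 and 0.840 without the filter, and 0.958 and 0.943 with probes above background on all arrays. A lone remaining array is assumed to vary like the other groups.

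A slide block was not run: it changes nothing within a slide and is confounded with LPS. List tests with a random mouse block were not run for genotype comparisons, fitting only the groups compared gives nothing further for the mean over times, and there is only 1 Commd1 probe. Signal over background limits folds of genes dim in 1 group, which are bounds.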

Other observations

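The tests of dendritic cell markers and of Lyz2 were chosen only after their results were seen, and the test of signal slope only after the covariances it concerns were seen.

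Maf, Tfeb, Ddit3, Hmox1 and Mt2 changed in opposite directions early and late after LPS in wildtype cells, and were chosen here for that after their values were seen. The macrophage transcription factor Maf fell by 2.51 ± 0.12 on the log2 scale at 3 h (SE, n = 2 per group) and rose by 2.28 ± 0.12 from 3 h to 24 h. Tfeb, a transcription factor for lysosome genes, fell by 3.11 ± 0.09 and rose by 3.03 ± 0.09. Ddit3, which encodes the stress factor CHOP, fell by 1.39 ± 0.10 and rose by 4.17 ± 0.10, and Hmox1, the heme oxygenase gene, fell by 0.84 ± 0.12 and rose by 2.53 ± 0.12. The metallothionein Mt2 went the other way, up by 3.39 ± 0.28 at 3 h and down from 3 h to 24 h at -5.43 ± 0.28. In knockout cells at 3 h Maf fell by 2.16 ± 0.12, Tfeb fell by 3.32 ± 0.09, Ddit3 fell by 1.44 ± 0.10 and Hmox1 fell by 0.71 ± 0.12, and Mt2 rose by 3.97 ± 0.28.

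By the detection of sex-linked genes, 0 of the 12 arrays differed from the others.

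In untreated knockout cells 18 of 32 interferon-stimulated genes and 10 of 15 MHC class II and costimulation genes were higher than in untreated wildtype. Both lists were called with the preset correlation but not an estimated one (adjusted p = 0.17 each). Of 10000 random lists matched on mean signal, 0 reached either list's median (0.66 and 0.80, highest matched 0.21 and 0.36). That mean included LPS arrays, so an array effect tied to untreated signal stays open. Both lists were already called and random lists ignore gene correlation, so the 0 bears only on signal level. Dendritic cell markers did not rise as a set, with a median of 0.08, or 0.03 with bounds, and a median absolute deviation of 0.37. More dendritic-like cells in the knockout cultures stay open, as a flat median cannot exclude cells with only a few of these markers. That untreated knockout cells stood partway along the 24 h LPS response may account for part of the differences: the covariance across genes of the genotype difference with the wildtype 24 h response was 0.096, against at most 0.031 in 100 simulations in which only the shared untreated wildtype arrays link them, and with the 24 h against 3 h response, which shares no array, it was 0.052 against at most 0.003. The 3 h response gave 0.044 against at most 0.031, so the excess was not confined to 24 h. The correlation with the 24 h response was small, with r of 0.20. Simulations, of independent noise with no mouse or LPS effect, gave a mean of 0.50. The spike-in slope was higher on the knockout than on the wildtype arrays and higher at 24 h, which could give such a covariance through signal level. Within 200 bins of the untreated level the covariance with 24 h against 3 h was 0.049 ± 0.0047 (SE across gene bins, not mice). In these arrays this argues against slope alone. Effectors, cytokines and chemokines rose at 24 h in wildtype cells (medians 2.61, 1.80 and 1.73). In untreated knockout cells they were not called (0.13, 0.32 and 0.30, each 0.00 with bounds), which a small shift allows. Il1rn went the other way (5.64 with LPS, -1.65 in untreated knockout cells). Other differences between array positions, which go with genotype, stay open. List medians resembling the response had been seen before the prediction. Whether a culture or mouse difference other than Commd1 underlies it was not tested.

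The genes called between untreated knockout and wildtype cells could come from a passenger region around the targeted allele. Genes within 10 Mb of Commd1 made up 0.58% of the calls, but with 117 genes there and 1547 calls elsewhere they could not have made up most. Of these 117 genes 9 (7.69%) were called against 6.82% elsewhere, a share above that of 68.4% of like windows. The region thus held no marked excess of calls. For those 9 genes the explanation stays open.

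Lyz2, the lysozyme gene, was lower in knockout than in wildtype cells after 3 h and 24 h of LPS (-0.63 and -1.13 on the log2 scale), and loss of 1 of 2 alleles, as in a Cre knock-in at this gene, is a candidate explanation. In untreated cells the difference of -0.39 ± 0.12 (SE, n = 2 per group) did not pass (adjusted p = 0.0912), while such a loss would lower it by 1 times the spike-in slope (0.735 on the flatter of these arrays). The untreated value argues against a constant loss, and compression of bright signals, which would shrink it, stays open.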
